A study of Homo sapiens with 10 samples.

How the data were processed

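RNA of the human cholangiocarcinoma (bile duct cancer) line HuCCT1, carrying either an empty vector or a construct labelled YAPS94A, was hybridised to Affymetrix arrays, 5 arrays per vector. Per the labels' protocols, total RNA was amplified with a NuGEN Ovation kit and biotin-labelled cDNA was hybridised. The values are the deposited log2 signals of 54675 probe sets, which lay between 2.86 and 14.43 on the 10 arrays. How the authors summarised and normalized the probes into these log2 values is not given in the sources used here. Array medians lay between 6.25 and 6.28 and the quartiles were nearly equal, so the deposited log2 values were used without further normalization. An array signal carries no count of molecules, and no detection calls were used here, so the precision rests on the number of arrays.

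Probe sets were named from the platform annotation, with symbols updated through a RefSeq table of the assembly GRCh38.p14, which served only for names and for the order of neighbouring genes. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none. The RefSeq table held 41043 of the 41097 with 1 symbol. The 62 control probe sets were left out of all tests. Each gene was represented by the probe set with the highest mean over the 10 arrays among those with 1 symbol, which gave 19775 genes. No genome coordinates are given, because the array values name no build.

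The vectors were compared with limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes on the log2 values of the 10 arrays with no covariate, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Differences are YAPS94A minus empty vector, with their standard errors (SE) from this fit. The 32 gene lists and 4 lists of markers of other cell types were fixed before the data were examined, as were the tests and the rule for naming genes. Each list was tested with camera, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, whereas fry asks whether the genes of a list moved, on balance, one way.

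The named genes were YAP1, the 12 genes with the largest rise and the 12 with the largest fall among genes past the test whose groups did not overlap, 5 well-known TEAD targets, and MFAP5, VEGFA, BIRC5 and MYC whatever their result. The rule also took the 4 members with the smallest p in the list's direction from each list past camera, and up to 3 members from any other list. GBP1, IRF9, CCL2, PTGS2, SREBF2, LATS1, MYOF, ARHGEF17 and the TEAD genes are named besides, as are IFI44L, IFI35, CXCL10, IL7, IL15, IL15RA, IL11, IL1B, MUC4 and MUC20 from the search of gene families and the genes that bound stretches of neighbours, and all of these were chosen after their values were seen. Genes read by a probe set whose identifier ends in _x_at are said to be open to cross-hybridisation.

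No label says whether the 5 arrays of a vector came from separate cultures, so p-values measure the spread between these arrays, which may be technical. No 2 arrays held identical values. Correlations between arrays over all probe sets were 0.9957 to 0.9991 within a vector and 0.9867 to 0.9902 between vectors. Both vectors share the numbers 1 to 5 in their labels. The deviations of same-numbered arrays from their group means correlated at 0.102 to 0.59 over the genes tested, above 0.1 in all 5 pairs. The numbers were therefore treated as a possible pairing. Over all probe sets the range was 0.065 to 0.542, and 4 of the 10 arrays correlated best with their own number. The pairing comes from this check and not from a stated batch. The main fit, with its SEs and adjusted p-values, has no block, as planned. Values with the number as a block are given where they change a call.

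The fit was tested on simulated data of the same 19775 genes, with 50 genes shifted at each size. It recovered 42% of genes shifted by 0.25 log2 units, 98% at 0.5 and 100% at 1 and at 2, with 6 false calls. Few genes were shifted there and the noise was independent between genes, whereas 36.3% of the real genes passed. These rates therefore need not hold for the real arrays. In a separate simulation with 1 list shifted by 0.25, camera called 1 of 36 lists, the shifted one. Its genes were drawn independently, so it does not measure false list calls where genes are correlated. Alternatives covered 2 renormalizations, 2 filters on dim genes, 2 other ways to represent a gene, another variance model, array weights, the block, each array left out in turn, 2 other set tests and all probe sets. After the data were seen, 3 more were added, which were a covariate for RNA quality, leaving out the arrays numbered 1 and 2, and removing the median difference of each gene's 30 nearest neighbours among genes above the median level.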

Results

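The transcriptome of HuCCT1, an established line of human intrahepatic cholangiocarcinoma, was measured on 10 arrays. 5 arrays held cells with an empty vector and 5 held cells with the construct labelled YAPS94A. YAP1 is the transcriptional co-activator that the Hippo kinase cascade keeps out of the nucleus. The sample labels and the series title name S94A, a substitution known to weaken binding of YAP1 to its TEAD partners. The series' design text instead names S127A, which removes an inhibitory phosphorylation site and gives a constitutively active protein. The array values do not show which of these the cells carried, and the construct is therefore called by its sample label throughout. The comparison asks how overexpression of this YAP1 construct changed the transcriptome.

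The YAP1 transcript was higher in the cells with the construct labelled YAPS94A, by 1.44-fold. The brightest of its 3 probe sets, chosen by the rule on mean level, read 12.32 ± 0.22 with empty vector and 12.85 ± 0.18 with the construct (log2 signal, mean ± SD, n = 5 each). The difference was 0.52 ± 0.11 (SE, limma adjusted p = 0.00277). The other probe sets of YAP1 rose by 0.60 ± 0.065 and 0.56 ± 0.10. On each of the 3 probe sets every construct array lay above every empty vector array, which gave an exact two-sided permutation p of 0.0079, the smallest that 5 against 5 allow. Permuting within the 5 pairs of same-numbered arrays gave an exact p of 0.0625 for each, the smallest that 5 pairs allow, so that scheme cannot pass 0.05. Genes around YAP1 in chromosome order were also higher, with a median of 0.26 over the 30 nearest genes above the median level, and subtracting the YAP1 neighbour median (0.31 in the version used for all genes) left 0.215 with the same SE (adjusted p = 0.144). Over all alternatives the adjusted p of the YAP1 level ranged from 6.16e-06 to 0.144.

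**Figure D1:**
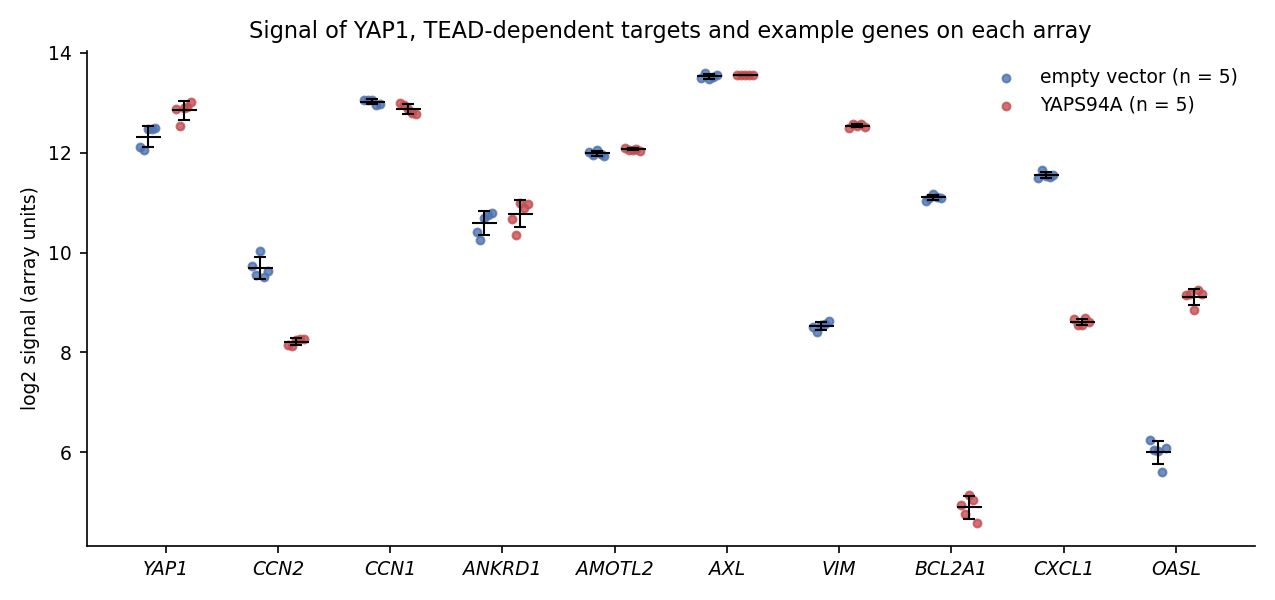
Log2 signal of YAP1, 5 TEAD targets and 4 strongly changed genes on each array, with empty vector in blue and YAPS94A in red (n = 5 each, points are arrays, bars are mean ± SD). YAP1 differed by 0.52 log2 units, CCN2 by -1.48, and BCL2A1 by -6.21.

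Many genes differed between the vectors, most of them by little. Of 19775 genes, 7172 (36.3%) passed the test, 3688 higher and 3484 lower with the construct. Only 647 of these differed by at least 2-fold, 401 higher and 246 lower, while 5533 differed by under 1.5-fold. The groups did not overlap for 5760 of the 19775 genes (29.1%), where chance would separate 0.794%, and 5605 of these 5760 passed the test. At 8-fold or more, 24 genes were higher and 41 were lower.

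The largest rises were in PLCB4, a phospholipase C of the beta class (5.87 ± 0.16, 58.5-fold), SLC6A14, an amino acid transporter (5.57 ± 0.13), and CALB1, the calcium-binding protein calbindin (5.16 ± 0.11). VIM, the intermediate filament protein vimentin, went from 8.53 ± 0.08 to 12.54 ± 0.04 (mean ± SD, n = 5), a 16.2-fold rise. CMPK2 and RSAD2, both interferon-induced, rose by 3.995 ± 0.19 and 3.72 ± 0.24. The other genes among the 12 largest rises were LINC01224 (4.67), the receptor gene GPR158 (4.08), LYPD6 (3.92), SAMD5 (3.804), the amino acid transporter gene SLC38A4 (3.59) and SFTA1P (3.58). The lower group mean lay below 4.73, the lower quartile of signals, for 3 of these 12, SLC6A14, GPR158 and RSAD2, and there a fold is less certain. LINC01224 (5.04), SLC38A4 (5.22), CMPK2 (5.23) and PLCB4 (5.63) also started low with empty vector, so the size and rank of their rises are uncertain too.

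The largest falls were in BCL2A1, an anti-apoptotic member of the BCL2 family (-6.21 ± 0.091, 74.0-fold), SDC2, the heparan sulfate proteoglycan syndecan-2 (-5.69 ± 0.097), and BCAT1, which transaminates branched-chain amino acids (-5.65 ± 0.12). GLUL, which encodes glutamine synthetase, fell by 5.09 ± 0.064. SRGN, the proteoglycan serglycin, went from 11.27 ± 0.025 to 6.49 ± 0.052 (mean ± SD, n = 5). POSTN, the matrix protein periostin, fell by 5.02 ± 0.097 and TRPC4, a cation channel, fell by 5.03 ± 0.078. The other genes among the 12 were ZNF662 (-5.13), the claudin gene CLDN11 (-5.04), AUTS2 (-4.81), DCDC2 (-4.47) and LRRN1 (-4.41). The mean with the construct was below 4.73 for ZNF662, CLDN11, POSTN and AUTS2. It was little above that for TRPC4 (4.86), BCL2A1 (4.90) and DCDC2 (4.92), and SDC2 was at 5.42. Without detection calls, background may limit all these falls, so their size and rank are uncertain.

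Probe sets of a gene did not always move alike. The second PLCB4 probe set rose by more than the chosen one, by 8.14 ± 0.17 from 4.13. The only GLUL probe set without an _s_at suffix lay near background in both groups (3.43 and 3.41) and decides nothing about the fall. The dimmer CLDN11 probe sets differed by 0.041 (from 5.95) and -0.001 (from 3.82). The dimmer probe set of VIM differed by 0.20 ± 0.077 (adjusted p = 0.0751 over all probe sets), and both dimmer probe sets of AUTS2 differed by 0.064 and -0.048. VIM, SAMD5, SFTA1P and BCAT1 lay in stretches of neighbouring genes that shifted together, with neighbour medians of 0.82, -0.38, 0.59 and -0.36, and the neighbours of GPR158 had a median of 0.67.

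**Figure D2:**
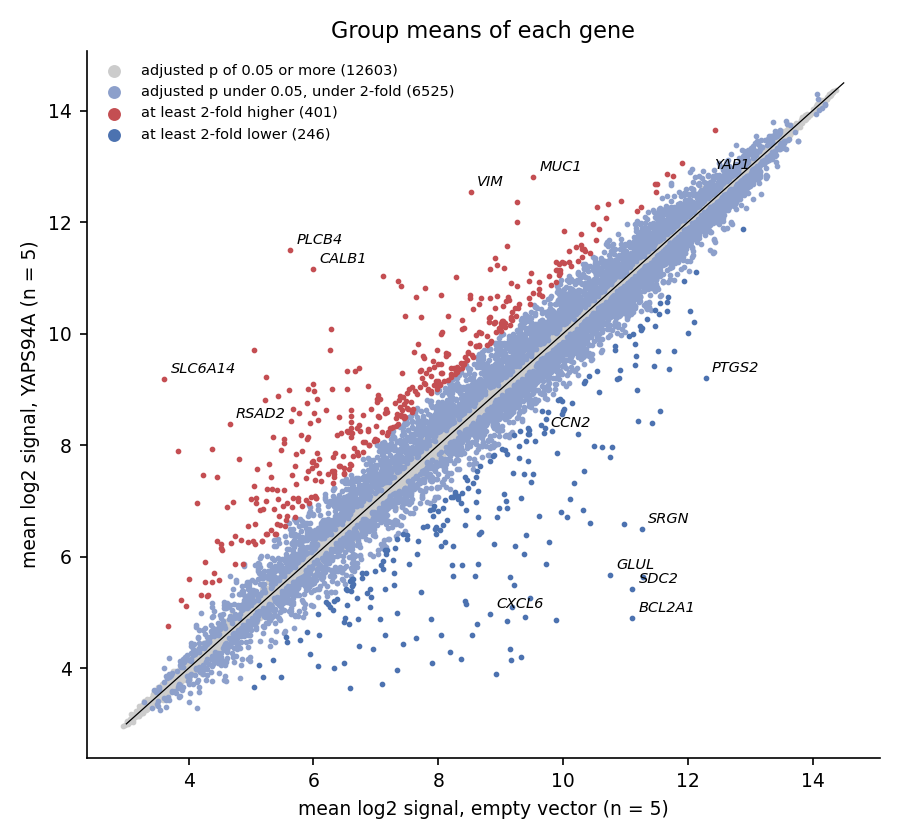
Mean log2 signal of each of 19775 genes with empty vector (x axis) and YAPS94A (y axis), 5 arrays each, with genes at least 2-fold higher in red (401) and at least 2-fold lower in dark blue (246). BCL2A1, SDC2, GLUL and SRGN lie far below the diagonal and PLCB4, CALB1 and VIM far above it.

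The known targets of YAP1 and TEAD, as a list, did not pass camera against other genes. Of 21 measured members of the list, 4 were higher, 1 was lower and 16 did not pass, with the same counts higher and lower when adjusted over the list alone. The list had a median difference of 0.084 and a camera adjusted p of 0.344 (adjusted p = 0.676 with an estimated correlation). Fry, which asks only for a net direction, gave 0.0175, upward. CCN2 (CTGF), a matricellular growth factor and standard readout of YAP1 activity, fell from 9.69 ± 0.22 to 8.21 ± 0.07 (mean ± SD, n = 5), a 2.79-fold decrease (-1.48 ± 0.090, adjusted p = 1.08e-07). CCN2 lay in a stretch of neighbours with a median of -0.35. The genes that rose were RBMS3, an RNA-binding protein gene (0.90 ± 0.12), NT5E, the ecto-nucleotidase CD73 (0.45 ± 0.034), ARHGEF17 (0.41 ± 0.12) and MYOF (0.25 ± 0.059). ARHGEF17 was at 0.162 relative to its neighbours. Another NT5E probe set went the other way (-0.58 ± 0.14).

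The other standard targets differed by less. CCN1 (CYR61) differed by -0.137 ± 0.051 (adjusted p = 0.056), and on its second bright probe set by -0.225 ± 0.045 (adjusted p = 0.0023 over all probe sets). ANKRD1 differed by 0.196 ± 0.14 (0.326), AMOTL2 by 0.083 ± 0.035 (0.0876) and the receptor tyrosine kinase gene AXL by 0.030 ± 0.033 (0.551). With the array number as a block, CCN1 (adjusted p = 0.0187) and ANKRD1 (0.00525) passed. CCN1 also passed without YAPS94A array 1 (0.0216) or YAPS94A array 2 (0.0378), and ANKRD1 without the arrays numbered 1 and 2 (0.0114). Over all alternatives the adjusted p ranged from 0.00578 to 0.153 for CCN1, from 0.00525 to 0.595 for ANKRD1 and from 0.00323 to 0.235 for AMOTL2. AMOTL2 passed with array weights (0.0462), with the intensity trend (0.0476), with the RNA quality covariate (0.0398), among genes above the median level (0.0421) and without the neighbour median (0.00323).

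Components of the Hippo pathway went both ways, with 8 of 31 higher, 6 lower and 17 not past the test (camera adjusted p = 0.597, the same counts higher and lower over the list alone). NF2, the upstream tumour suppressor merlin, fell by 0.55 ± 0.043, among neighbours with a median of -0.29, and was at -0.257 relative to them. AJUBA, a LIM protein that restrains LATS kinases, rose by 0.47 ± 0.037 on its brightest probe set, while others almost as bright were at 0.245 and 0.216 and did not pass over all probe sets (adjusted p = 0.0814 and 0.0751). VGLL1, a TEAD cofactor, rose by 0.41 ± 0.037, and its other bright probe set by 0.58 ± 0.041. The call was lost without _x_at and _s_at probe sets, where the only VGLL1 probe set left read 4.93 and 4.91, too dim to decide. The kinase gene LATS1 fell by 0.75 ± 0.13, in a stretch of neighbours with a median of -0.38, and was at -0.365 relative to them. None of the 4 TEAD genes passed the limma test, with TEAD1, TEAD2, TEAD3 and TEAD4 at 0.011, -0.085, 0.169 and -0.032. The neighbours of TEAD4 had a median of -0.32.

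Interferon-stimulated genes rose together. Of 29 measured, 28 were higher and 1, GBP1, was lower (-0.36 ± 0.072), with a median difference of 1.04 or 2.06-fold (camera adjusted p = 1.05e-18, adjusted p = 0.0223 with an estimated correlation). The counts were the same adjusted over the list alone. MX2, an antiviral GTPase, rose by 3.57 ± 0.13 from a level below the lower quartile of signals (4.37 ± 0.24, SD, n = 5). OASL, of the oligoadenylate synthetase family, rose by 3.11 ± 0.11, IFIT3 by 1.496 ± 0.059 and IFI27 by 1.01 ± 0.039. IRF9, part of the interferon-activated transcription factor ISGF3, rose by 1.76 ± 0.10.

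Antigen presentation genes also rose, 12 of 17 higher and 5 not past the test (13 higher adjusted over the list alone), with a median of 0.43 (camera adjusted p = 2e-06). That call was lost with an estimated correlation (adjusted p = 0.0746). The immunoproteasome subunit genes PSMB9, PSMB10 and PSMB8 rose by 0.94 ± 0.034, 0.77 ± 0.048 and 0.55 ± 0.040. CD74, the invariant chain of class II molecules, rose by 0.73 ± 0.048.

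NF-kB and inflammatory genes fell. Of 24 measured, 19 were lower, 1 was higher and 4 did not pass (20 lower adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.43e-10, adjusted p = 0.00243 with an estimated correlation). The neutrophil-attracting chemokine genes CXCL6, CXCL1, CXCL3 and CXCL2 fell (-3.87 ± 0.085, -2.94 ± 0.043, -2.19 ± 0.054 and -1.83 ± 0.054). CXCL2 and CXCL8 (-2.09 ± 0.15) are read by _x_at probe sets and are open to cross-hybridisation. PTGS2, the inducible cyclooxygenase, fell by 3.08 ± 0.15. The exception was CCL2, a monocyte-attracting chemokine, which rose by 2.45 ± 0.10.

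Angiogenesis factors shared some of these falls. Of 20 measured, 7 were lower, 3 higher and 10 not past the test, with a median of -0.13 and a mean of -0.41 (camera adjusted p = 0.0277). The call was lost with an estimated correlation (adjusted p = 0.0832) and with the array number as a block (adjusted p = 0.0652), and over all alternatives the adjusted p ranged from 9.61e-10 to 0.0832. CXCL1 and CXCL8 are members of both lists. MFAP5, a microfibril protein, fell from 10.24 ± 0.05 to 8.20 ± 0.04 (mean ± SD, n = 5), a 4.10-fold decrease, in a stretch of neighbours with a median of -0.36. JAG1, a Notch ligand, fell by 0.42 ± 0.032. VEGFA, the main vascular growth factor, rose by 0.18 ± 0.047 (adjusted p = 0.00815).

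Of 23 listed cholesterol biosynthesis genes 17 were measured, and all 17 rose, with a median of 0.46 or 1.38-fold (camera adjusted p = 1.03e-09, adjusted p = 0.00902 with an estimated correlation). All 17 also passed adjusted over the list alone. SQLE, squalene epoxidase, rose by 0.80 ± 0.048, HMGCS1, the HMG-CoA synthase, by 0.56 ± 0.038 and FDPS, farnesyl diphosphate synthase, by 0.43 ± 0.034. IDI1 read 0.88 ± 0.038 higher, but on an _x_at probe set open to cross-hybridisation and in a stretch of neighbours with a median of 0.49. SREBF2, the transcription factor of the pathway, rose by 0.64 ± 0.10. Fatty acid synthesis genes were 8 higher and 3 lower of 16 (9 higher over the list alone, camera adjusted p = 0.0664, and adjusted p = 0.0494 with the array number as a block). ACSL1 and ACSS2, which activate fatty acids and acetate, rose by 0.84 ± 0.066 and 0.80 ± 0.073, and the acyltransferase gene GPAM fell by 0.73 ± 0.041.

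Genes of ribosome biogenesis and MYC targets fell, 20 of 23, with 3 not past the test (21 lower adjusted over the list alone) and a median of -0.37 (camera adjusted p = 5.51e-09). With an estimated correlation the adjusted p was 0.0685. NOP2, an rRNA methyltransferase, fell by 0.89 ± 0.072, PES1, needed for maturation of the large subunit, by 0.76 ± 0.053, ODC1, ornithine decarboxylase, by 0.73 ± 0.062 and LYAR by 0.56 ± 0.042. A dim second PES1 probe set differed by 0.18 ± 0.063. MYC itself varied widely between arrays of one vector (10.89 ± 0.50 and 10.84 ± 0.42, SD, n = 5) and differed by -0.046 ± 0.25 (adjusted p = 0.917). Ribosomal protein genes showed no call, with 0 of 24 past the test in limma (also 0 over the list alone and 0 at an unadjusted p under 0.05, camera adjusted p = 0.937) and RPS3, RPL8 and RPS9 at 0.055, 0.050 and 0.045. With the intensity trend RPS3 (adjusted p = 0.0034) and RPL8 (0.0381) passed. RPS3, RPL8 and RPS9 read 14.07, 13.88 and 13.59 with empty vector, near the highest signal on the arrays (14.43). Whether differences are compressed at that level was not tested.

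Histone genes fell, 8 of 10, with 2 not past the test (10 lower adjusted over the list alone) and a median of -0.54 (camera adjusted p = 2e-06, adjusted p = 0.0832 with an estimated correlation). H2BC4, H2BC21, H2BC9 and H2BC12, all encoding histone H2B, fell by 1.10 ± 0.080, 0.82 ± 0.051, 0.77 ± 0.049 and 0.61 ± 0.041. H2BC9 is read by an _x_at probe set, and histone genes resemble each other closely, so signal between them may be shared. DNA replication genes did not follow, with 5 of 30 higher and 2 lower (camera adjusted p = 0.393). The transcription factor gene E2F2 rose by 0.71 ± 0.050 and CDC45, a part of the replicative helicase, fell by 0.41 ± 0.043. MCM10 read 0.49 ± 0.058 higher among neighbours with a median of 0.71, and -0.218 relative to them. Among mitosis genes 2 of 30 were higher and 5 lower (camera adjusted p = 0.468), with PLK1, CENPE and BUB1 lower by -0.26, -0.24 and -0.20. BUB1 lost its call in the mean of its probe sets (-0.136). BIRC5 (survivin) differed by -0.035 ± 0.032 (adjusted p = 0.461), but a second bright probe set of BIRC5 was at -0.287 ± 0.051 (adjusted p = 0.00106 over all probe sets), and BIRC5 passed in the mean of its probe sets (-0.10) and relative to its neighbours (-0.217).

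Among RNA splicing factors 8 of 26 were lower and 1 higher (camera adjusted p = 0.0826, and adjusted p = 0.0466 with the RNA quality covariate). The kinase gene CLK4 rose by 0.45 ± 0.044, and SF3A1 and SRSF6 fell by 0.29 ± 0.051 and 0.18 ± 0.037. SF3A1 was at 0.004 relative to its neighbours, and SRSF6 lost its call in the mean of its probe sets (-0.104).

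**Figure D3:**
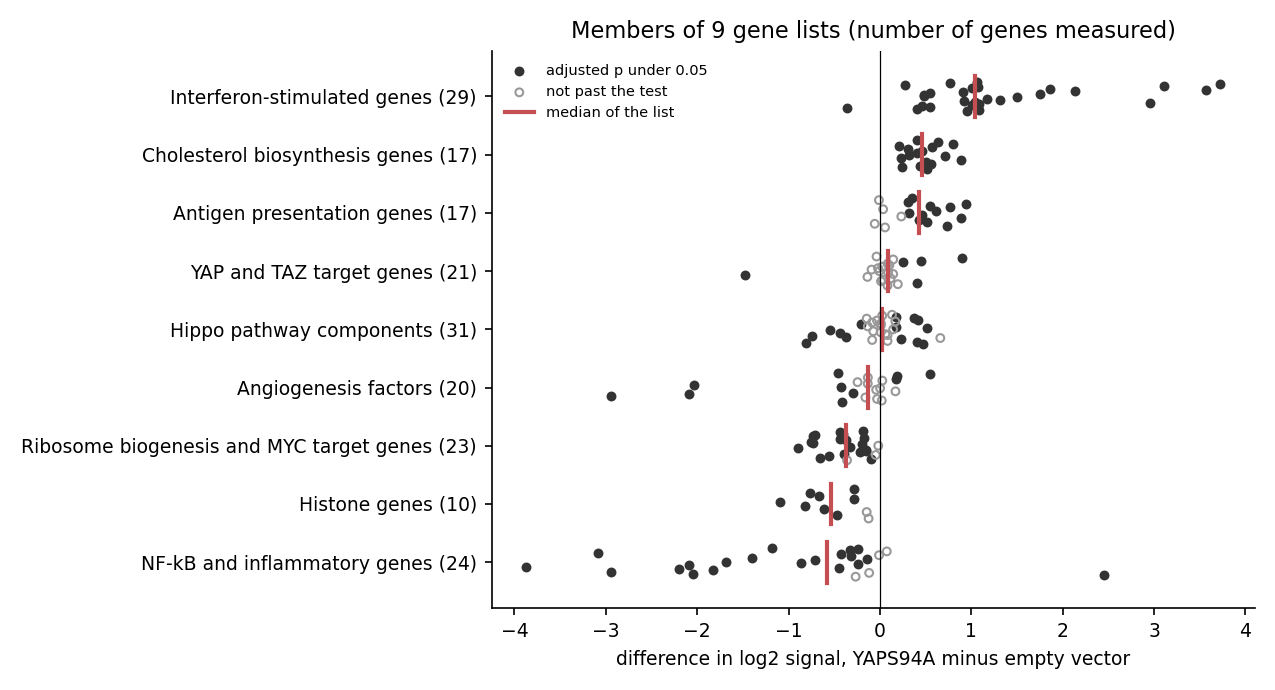
Difference in log2 signal (YAPS94A minus empty vector, n = 5 each) of each measured member of 9 gene lists, with filled points past an adjusted p of 0.05 and red bars at the list medians. The interferon list has a median of 1.04, the YAP and TAZ target list of 0.084 and the NF-kB list of -0.58.

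The epithelial and mesenchymal lists did not pass camera against other genes, although fry called both upward and single members changed strongly. Of 25 epithelial and bile duct genes 10 were higher and 4 lower (camera adjusted p = 0.124, fry adjusted p = 8.09e-07, upward). MUC1, a membrane mucin, rose by 3.29 ± 0.061 and CFTR, the chloride channel, fell by 3.90 ± 0.091 to a level below the lower quartile of signals. CLDN3, a tight junction protein gene read by an _x_at probe set open to cross-hybridisation, rose by 0.58 ± 0.045. Of 20 mesenchymal transition genes 3 were higher and 7 lower (camera adjusted p = 0.344, downward, with a median of -0.060 and a mean of -0.031, and fry adjusted p = 0.0048, upward). VIM rose as given above, while ZEB1, a repressor of epithelial genes, fell by 1.24 ± 0.058, and FN1 (fibronectin), read by an _x_at probe set open to cross-hybridisation, fell by 1.64 ± 0.061. ZEB1 lay in a stretch of mostly higher genes, although its 30 nearest had a median of only 0.058.

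Extracellular matrix and integrin genes were 6 higher and 8 lower of 25 (camera adjusted p = 0.468). The collagen gene COL5A2 fell by 3.32 ± 0.10 and TNC (tenascin C) by 1.35 ± 0.099. Actin cytoskeleton and SRF targets were 5 higher and 5 lower of 21 (6 and 6 over the list alone, camera adjusted p = 0.907, downward, with a median of -0.035 and a mean of 0.023). ACTA2, smooth muscle actin, rose by 2.21 ± 0.076, FHL2 rose by 0.40 ± 0.051, and TPM2, a tropomyosin in a stretch of neighbours with a median of -0.29, fell by 1.26 ± 0.048.

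Members of the signalling lists went both ways, and none of these lists passed camera. Fry, however, called the TGF-beta, Wnt and Notch lists downward (fry adjusted p = 0.000116, 0.00159 and 4.55e-05). It did not call the immediate early and ERK lists (fry adjusted p = 0.843 and 0.578). TGF-beta and SMAD targets were 8 higher and 5 lower of 22 (camera adjusted p = 0.962, downward, with a median of 0.004 and a mean of -0.094), with ID3 and LTBP1 lower by -1.05 ± 0.058 and -0.80 ± 0.065. Wnt targets were 1 higher and 6 lower of 18 (camera adjusted p = 0.246), with the Wnt inhibitor genes ZNRF3 and DKK1 lower by -0.73 ± 0.057 and -0.34 ± 0.034 and TNFRSF19 by -0.48 ± 0.13. ZNRF3 lay among neighbours with a median of -0.30 and was at -0.428 relative to them. Notch pathway genes were 2 higher and 5 lower of 17 (6 lower over the list alone, camera adjusted p = 0.36), with HEY1 and LFNG lower by -0.75 ± 0.061 and -0.55 ± 0.039. Immediate early genes were 5 higher and 7 lower of 22 (camera adjusted p = 0.812, downward, with a median of -0.033 and a mean of 0.028), with ATF3 and KLF4 up by 1.07 ± 0.040 and 0.71 ± 0.066 and JUN down by -0.60 ± 0.046. ERK output genes were 5 higher and 4 lower of 18 (6 higher over the list alone, camera adjusted p = 0.825), with the phosphatase gene DUSP5 up by 0.82 ± 0.059, and SPRY2 and IER3 lower by -0.62 ± 0.071 and -0.30 ± 0.031.

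Genes of p53 and p73 were 9 higher and 6 lower of 21 (10 higher over the list alone, camera adjusted p = 0.392). FAS, a death receptor, and SFN, 14-3-3 sigma, rose by 0.97 ± 0.035 and 0.62 ± 0.033, and TIGAR fell by 0.70 ± 0.041. Apoptosis regulators were 6 higher and 4 lower of 20 (camera adjusted p = 0.812, upward, with a median of -0.027 and a mean of 0.063), with the pro-apoptotic genes HRK and PMAIP1 up by 0.64 ± 0.064 and 0.28 ± 0.042. Drug transporters and drug metabolism genes were 6 higher and 7 lower of 21 (camera adjusted p = 0.567). The efflux pump gene ABCG2 fell by 0.66 ± 0.058, GSTM1, on an _x_at probe set open to cross-hybridisation, fell by 0.88 ± 0.099, and ERCC1, a nucleotide excision repair gene, read 0.37 ± 0.044 higher on its brightest probe set only, the others being at -0.001 and -0.017 at levels of 9.99 and 9.82.

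The lists of hypoxia, NRF2, amino acid response, heat shock, endoplasmic reticulum stress and oxidative phosphorylation genes did not pass camera. Hypoxia and glycolysis genes were 8 higher and 5 lower of 28 (adjusted p = 0.36), with NDRG1 up by 1.82 ± 0.078, BNIP3L by 0.51 ± 0.035 and PFKFB3, among neighbours with a median of 0.55, by 0.69 ± 0.036. NRF2 targets were 5 higher and 6 lower of 19 (6 and 6 over the list alone, adjusted p = 0.698), with HMOX1, heme oxygenase 1, down by -0.64 ± 0.058. AKR1C1 and AKR1C2 read -0.76 ± 0.072 and -0.91 ± 0.072, but are near-identical and open to cross-hybridisation on _x_at probe sets, and both calls were lost without _x_at and _s_at probe sets, where the probe sets left read 5.15 (AKR1C1) and 4.21 (AKR1C2) with empty vector, too dim to decide. Their neighbours had a median of 0.51. Amino acid response genes were 3 higher and 6 lower of 21 (adjusted p = 0.36), with VLDLR, among neighbours with a median of -0.31, down by -1.17 ± 0.083 and CTH by -0.43 ± 0.058. ASNS, asparagine synthetase, rose by 0.46 ± 0.068. Its call was lost without _x_at and _s_at probe sets, where the only ASNS probe set left read 4.42 and 4.37, too dim to decide.

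Heat shock genes were 1 higher and 5 lower of 14 (camera adjusted p = 0.468), with the small heat shock protein gene HSPB1 up by 0.79 ± 0.051 and HSPH1 down by -0.26 ± 0.042. DNAJA1 read -0.21 ± 0.031, among neighbours with a median of -0.33, and 0.123 relative to them. Endoplasmic reticulum stress genes were 4 higher and 3 lower of 21 (5 higher over the list alone, camera adjusted p = 0.552). XBP1 fell by 0.22 ± 0.044, a call lost in the mean of its probe sets (-0.093) and turned to 0.08 relative to its neighbours. HERPUD1 read 0.14 ± 0.036 and lost its call in the mean of its probe sets (0.084), and HSP90B1, on an _x_at probe set open to cross-hybridisation, rose by 0.16 ± 0.042. Oxidative phosphorylation genes were 4 higher and 4 lower of 29 (camera adjusted p = 0.966), with NDUFA2 up by 0.35 ± 0.034 and NDUFB3 down by -0.33 ± 0.033. Their neighbours had medians of 0.21 and -0.23, and relative to them the differences were 0.144 for NDUFA2 and -0.099 for NDUFB3. ATP5F1C read 0.31 ± 0.029 higher on an _x_at probe set open to cross-hybridisation, and -0.271 relative to its neighbours.

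Markers of cell types that the culture should not hold did not pass camera against other genes, while fry called the fibroblast and leukocyte lists downward. Fibroblast markers were 2 higher and 3 lower of 14 (camera adjusted p = 0.597, fry adjusted p = 0.000369), with LUM and FBLN1 up by 2.67 ± 0.088 and 1.39 ± 0.057 and POSTN down as given above. Leukocyte markers were 3 lower of 12 and 9 not past the test (camera adjusted p = 0.251, fry adjusted p = 0.000123), with LCP1, an actin-bundling protein gene, down by -3.03 ± 0.11 and LYZ and FCER1G by -1.48 ± 0.12 and -0.33 ± 0.062. Without _x_at and _s_at probe sets LYZ and FCER1G lost their calls, but the LYZ probe set left read only 3.70 with empty vector and that of FCER1G 5.08 (-0.229). Hepatocyte markers were 1 higher and 3 lower of 16 (camera adjusted p = 0.812, downward, with a median of 0.009 and a mean of -0.015), with FGB, SERPINA1 and CYP2E1 at -0.38, -0.19 and 0.39. Endothelial markers were 1 higher and 1 lower of 12 (0 lower over the list alone, camera adjusted p = 0.966, upward, with a median of -0.017 and a mean of 0.015). ESAM rose by 0.42 ± 0.078, CLDN5 was at -0.16 (adjusted p = 0.0376) and TEK at -0.14 (0.0758, and 0.0132 with the array number as a block). TEK passed without YAPS94A array 2 (0.046) and turned to 0.194 relative to its neighbours. The CLDN5 call was lost without empty vector array 1 (0.0792), 2 (0.0781), 3 (0.0523) or 5 (0.0635), and without YAPS94A array 1 (0.0866), 3 (0.0832) or 4 (0.0846). Over all alternatives the adjusted p ranged from 0.00821 to 0.999 for CLDN5 and from 0.0132 to 0.175 for TEK.

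Some further genes named above moved by over 1.5 times once the neighbour median was removed, all still past the test in the same direction. CDC45 was then at -0.253, PLK1 at -0.164, TIGAR at -0.435, HSPH1 at -0.173, SRSF6 at -0.114 and PES1 at -0.467. CLK4 was at 0.293, IDI1 at 0.391, PFKFB3 at 0.145, AKR1C1 at -1.279 and AKR1C2 at -1.42.

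With an estimated correlation, camera kept 3 of the 7 calls over the 36 lists, those of the interferon, NF-kB and cholesterol lists. Fry called 26 lists, 11 upward and 15 downward. Upward calls that camera lacked included p53 and p73 (fry adjusted p = 8.95e-06), hypoxia (0.000114), fatty acid synthesis (0.000202), apoptosis (0.000498) and endoplasmic reticulum stress (0.00544). Downward calls that camera lacked included splicing (fry adjusted p = 0.000202), drug (0.00111), matrix (0.00416), amino acid (0.0193), NRF2 (0.0215) and heat shock genes (0.0237). Where no separate count is given for a list, the counts adjusted over the list alone equalled those over all genes.

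**Figure D4:**
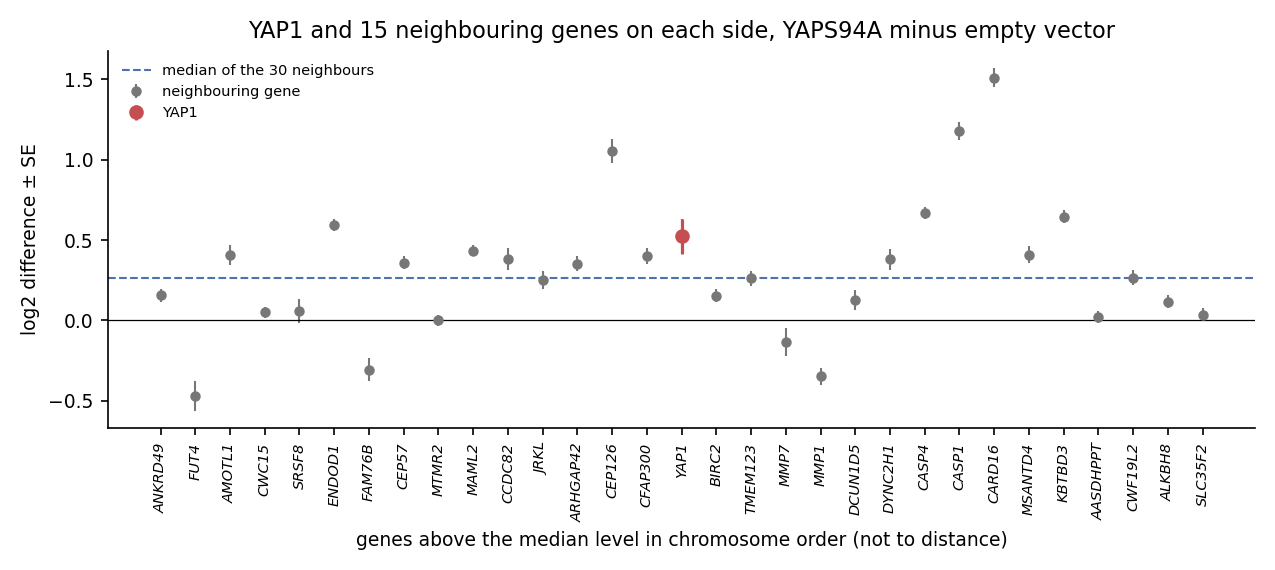
Difference in log2 signal (YAPS94A minus empty vector, ± SE, n = 5 each) of YAP1 in red and of the 15 genes above the median level on each side of it, in chromosome order from ANKRD49 to SLC35F2, not drawn to distance. The dashed line marks the neighbours' median of 0.26, and 6 of the 30 lie above YAP1.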

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

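In 13 of 280 groups of 5 arrays (140 named genes in each vector), 1 array stood apart from the other 4, with a gap to its nearest neighbour above 0.71 of the whole range of the group. That is 4.6% of groups, and chance gives about 1 in 20. In YAPS94A array 2, POSTN (4.45 against 4.05 to 4.12 in the others) and MCM10 (10.38 against 10.16 to 10.19) were high, and SPRY2 (9.65 against 9.91 to 9.95) and ZEB1 (7.13 against 7.34 to 7.38) were low. In YAPS94A array 3, OASL was low (8.84 against 9.14 to 9.24) and CXCL3 was high (9.16 against 8.93 to 8.97). AKR1C2 was low in YAPS94A array 5 (8.59 against 8.86 to 8.94). With empty vector, SDC2 was high in array 2 (11.37 against 11.02 to 11.07), FDPS was high in array 1 (13.44 against 13.34) and GPAM was high in array 3 (9.83 against 9.71 to 9.74). RPL8 was low in array 3 (13.83 against 13.88 to 13.90), and XBP1 (9.59 against 9.66 to 9.69) and FCER1G (5.35 against 5.52 to 5.57) were low in array 4.

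Probe sets with no gene symbol or with several were named in no comparison, yet 2494 of 13522 of them passed the same limma test over all probe sets, 1075 higher and 1419 lower with the construct, and 109 of these differed by at least 2-fold.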

How the results depend on the processing

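The 3 alternatives with the RNA quality covariate, without the arrays numbered 1 and 2, and with the neighbour median removed were chosen after the data were seen. Over 1608 values of the named genes under alternatives other than leaving out single arrays, 1563 kept their direction and side of the threshold, 12 lost the call, 21 gained one and 12 turned in sign. With single arrays left out, 1376 of 1390 values were the same. Of 98 values of the 7 called lists, 93 kept the call, and none of 70 was lost with single arrays left out. With single arrays left out, genes changed ranged from 6524 to 7206, genes changed at least 2-fold from 637 to 666, the YAP1 difference from 0.454 to 0.601, the adjusted p of the YAP and TAZ target list from 0.162 to 0.451 and the called lists from 7 to 8. MYC, at -0.046, was the only named gene to change sign there (range -0.231 to 0.119), to 0.086, 0.016 and 0.007 without empty vector arrays 3, 4 and 5 and to 0.119 without YAPS94A array 2.

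With the array number as a block 8154 genes changed, 7046 of them shared, 647 by at least 2-fold, and 7 lists were called, 6 of them shared. Apart from the lists of angiogenesis factors and fatty acid synthesis and the genes CCN1, ANKRD1 and TEK, the block changed no call of a list or a named gene. Only 363 genes changed at least 2-fold among genes above the median level, where fewer genes were tested. All probe sets in place of 1 per gene gave 15643 calls, since more were tested. The lists called fell to 3 with an estimated correlation and rose to 26 with fry, and fry called the YAP and TAZ target list at 0.0175, where its other adjusted p ranged up to 0.676. These tests ask different questions. Without _x_at and _s_at probe sets VGLL1 turned to -0.019, ASNS to -0.056 and RPS9 to -0.024, read by the only probe sets left, which are dim (4.93, 4.42 and 5.45 with empty vector), so these turns say nothing about the genes. With the neighbour median removed the YAP1 level fell from 0.523 (adjusted p = 0.00277) to 0.215 (adjusted p = 0.144) and lost its call. AXL turned to -0.02, MCM10 to -0.218, XBP1 to 0.08, DNAJA1 to 0.123, ATP5F1C to -0.271, RPS3 to -0.072, RPL8 to -0.126, SF3A1 to 0.004 and TEK to 0.194, by construction of that correction. The planned pseudocount alternative was not run, because the values are log2. Genes below 4.73, the lower quartile of signals, are read close to background, and their folds are limited by it. The same may hold for genes a little above that level.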

Other observations

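The search of gene families, the tests of YAP1's neighbours and vector and both tests of the second principal component were chosen only after the results were seen. Among 683 families of genes that share a symbol stem, 3 held more genes changed at least 2-fold than a draw of independent genes would (hypergeometric test, Benjamini-Hochberg adjusted). Members of a family may move together, so these p-values do not measure what chance gives. Most of the changed IFI and CXCL genes are also members of the interferon or NF-kB lists, so they add no separate support. Of 8 IFI genes 5 rose at least 2-fold (adjusted p = 0.000982), among them IFI44L (2.95 ± 0.14) and IFI35 (1.499 ± 0.068). Of 14 CXCL genes 6 changed (adjusted p = 0.000982), CXCL10 upward (1.09 ± 0.14) and CXCL6, CXCL1, CXCL3, CXCL8 and CXCL2 downward. Of 88 genes with the stem IL, interleukins and their receptors, 11 changed (adjusted p = 0.0313), 8 upward and 3 downward. IL7, which supports lymphocyte survival, rose by 1.76 ± 0.077, IL15 by 1.46 ± 0.061 and its receptor gene IL15RA by 1.33 ± 0.054 (0.833 relative to its neighbours), while IL11, of the IL-6 family, fell by 2.81 ± 0.073 and IL1B by 1.69 ± 0.072. The mucin genes MUC1, MUC4 and MUC20 were higher by 3.29, 2.67 and 1.26. These 3 of 18 MUC genes did not pass the same test after adjustment over the 683 families (unadjusted p = 0.0197, adjusted p = 0.764).

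Other splits of the 10 arrays into 5 and 5 were compared with the real one, with 100 of 126 splits drawn. No other drawn split gave as many changed genes, 7172 against at most 126 (1 of 100 splits as large, the real one). None gave as many changed at least 2-fold, 647 against at most 0 (1 of 100). The other splits mix the vectors, so the vector difference adds to their spread and few genes can pass. These counts show that the arrays part by vector. They cannot exclude a chance difference between 2 cultures, as no label says that the arrays are separate cultures. The number of called lists did not stand out, as 20 of 100 splits gave 7 or more and the highest of the others gave 9. Nor did the YAP and TAZ target list, where 50 of 100 splits gave a camera p as small as the real 0.134, the smallest of the others being 0.000185. For single lists the real split gave the smallest p, 1 of 100, for the interferon, NF-kB, antigen presentation, cholesterol, ribosome biogenesis and angiogenesis lists. The smallest p of the other splits was 1.44e-13 against 2.93e-20, 6.64e-08 against 7.95e-12, 7.88e-06 against 3.1e-07, 5.27e-09 against 8.55e-11, 3.77e-09 against 6.12e-10 and 0.00588 against 0.00539, in that order. For the histone list 2 of 100 splits gave a p as small as 3.34e-07, the smallest being 2.21e-07. Among the 16 splits that part all 5 pairs, as the real one does, the highest of the others gave 0 changed genes and 8 called lists. Each of the other splits still puts more arrays of 1 vector on one side, and so keeps part of the vector difference. Lists called in them therefore do not measure what chance alone gives.

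Genes next to each other on a chromosome shifted together, and over 9869 genes above the median level the rank correlation of neighbours' differences was 0.213, against at most 0.034 in 1000 shuffles of gene order, but splits within one vector reached 0.224, so array or RNA quality remains open for this correlation. It was 0.197 without neighbours that share a symbol stem, which argues against clusters of similar genes as its whole source. In longer stretches, 9 runs of at least 30 genes had medians beyond the highest of 200 shuffles (0.33). Of these, 1 went upward, from ZMYND11 to ARHGAP12 (75 genes, median 0.617, 66 higher), and 8 downward, such as REV3L to PEX7 (median -0.37, 58 of 60 lower). Splits within one vector gave at most 0.241, against 0.819 between vectors. All 9 runs kept their sign with the RNA quality covariate. That covariate was nearly balanced between the vectors (1.13 with empty vector and 1.01 with the construct), so it could hardly turn a sign and decides little. A regional difference in gene dosage between the cultures remains a hypothesis that these tests leave open. Genes 10 places apart correlated at 0.107, but 5 of the 20 splits within one vector reached as much (up to 0.154), so this value decides nothing, and an effect of the construct on whole regions was not tested.

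The rise of YAP1 has more than one possible explanation. A shift of its neighbourhood may account for it in part or in whole, since the 30 nearest genes had a median of 0.264 and 6 of them lay above YAP1. However, YAP1 lay in none of the 9 runs, and this median was below the 0.33 that runs had to pass. None of 10000 random draws of 30 genes had so high a median (permutation p = 1e-04, the smallest that these draws can give), although such draws ignore that neighbours move together elsewhere too. The alternative, that the probe sets read the vector's transcript, cannot be told apart from it. The smallest rise among the 3 probe sets was 0.523, but where they lie in the transcript is not given in the sources used here, and a transcript of the coding sequence alone might escape them.

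The second principal component (9.8% of the variance, after 81.1% for the vectors) spread the arrays alike in both groups. It followed the difference between the 3' and 5' probe sets of the actin control over the 10 arrays (Pearson r = 0.955, permutation p = 9e-05, Spearman rho = 0.891, permutation p = 0.001, 1 relation computed), and r was 0.894 without the 2 arrays farthest from the median actin difference, which is consistent with RNA quality or amplification bias as its source. Its difference between the vectors (exact permutation p = 0.96) is held near 0 because the first component already parts them, and decides nothing. The actin difference was 1.13 ± 0.27 with empty vector and 1.01 ± 0.28 with the construct (SD, n = 5 each, exact permutation p = 0.484, and 0.312 permuting within pairs), and no biological explanation was tested.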
